A study of Homo sapiens with 3 samples.

How the data were processed

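RNA sequencing was performed on 3 established human prostate cancer cell lines, LNCAP, PC3 and DU145, with 1 library per line. Per the labels' protocols, the lines were kept at 37 °C and 5% CO2 in medium with 10% fetal bovine serum, RNA was extracted with TRIzol and a column kit, and 4 ug of total RNA went into each library. The labels name several media in a row without saying which line received which, so no medium is assigned to a line here. The grouping by line was taken from the cell line label of each sample, and the series design places LNCAP in the androgen-dependent class and the other 2 lines in the castration-resistant class.

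The authors deposited a table of raw read counts per gene for each library, with whole numbers and no normalization. They also deposited a table of FPKM values per gene for each library. In these tables each FPKM equalled the deposited count divided by the listed gene length and by 1 constant per library, so FPKM is another scaling of the same counts; the constant was 1.034, 1.005 and 0.988 times the count total in LNCAP, PC3 and DU145. The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1 without their roles. The program that counted the reads, its strand setting and the genome build are not given in the sources used here. All 58735 gene identifiers and their coordinates matched GENCODE release 29, so coordinates are given on GRCh38. Because the handling of reads that match several places is unknown, values of genes with near-identical copies or overlapping gene models are uncertain. This holds for the MAGEA, GAGE, XAGE, UGT2B, AKR1C and HLA genes, for FOLH1 and ANXA2, for SULF2 and CCDC141, which overlap other genes, and for FAM83A and others with an antisense partner.

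Library totals were 15393103 counts for LNCAP, 15319045 for PC3 and 15878546 for DU145. Counts were scaled with TMM factors of 1.016, 0.998 and 0.987 (edgeR 4.0.16 in R 4.3.3), and levels are given as normalised CPM. The 18025 genes at 1 CPM or more in at least 1 library were compared. For each pair of lines the ratio of scaled counts was computed with its exact 95% counting interval (conditional binomial, Clopper-Pearson; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). A gene was called 4-fold apart when its log2 ratio, with 0.5 counts added, was at least 2 in size and the interval excluded a ratio of 1. Against a count of 0, the fold is a bound computed with 3 counts in that library, written as "at least". No fold is given where both libraries had 3 counts or fewer. Reads without molecular identifiers are not independent molecules, and the intervals and bounds cover counting error only. They compare these libraries, not the classes.

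For the class comparison, edgeR's quasi-likelihood test was fitted to PC3 and DU145 as 2 libraries against LNCAP, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. It treats the difference between PC3 and DU145 as the spread within the class. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. Because both comparisons with LNCAP share its library, unchanged libraries were simulated, with Poisson counts and with gamma-Poisson counts at an assumed biological coefficient of variation of 0.4, in 20 simulations each.

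The gene lists, the rule for named genes, the tests of each comparison and most alternatives were fixed before the data were examined. Lists covered 22 subjects, from androgen response to housekeeping, plus a list of genes that tell the lines apart. Older symbols in the lists were matched to those in the files (CTSL1, IL8, PKM2, PVRL4 and SC5DL to CTSL, CXCL8, PKM, NECTIN4 and SC5D). A list's median log2 ratio was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart when its median lay outside the middle 95% of them. This percentile describes these libraries and is not a p-value. Where members had no counts in a library, the median was also computed with these members at their bound.

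Named genes were those with the largest near bound of the counting interval, among protein-coding and lincRNA genes and leaving out mitochondrial, ribosomal protein and Y-linked genes. They were the 10 genes each way in both lines against LNCAP, the 5 each way apart from LNCAP in 1 line and under 2-fold apart in the other, and the 8 each way between PC3 and DU145. From each list the 2 to 4 members with the largest ratios, any member that went against the list, and the genes that tell the lines apart were also named. Some of these genes and 1 list are not reported here. Other list members named in the text, the genes around STAT3, and the further groups at the end were chosen after their values were seen.

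The ratio calls were tested on simulated Poisson counts with known 8-fold differences. These counts hold counting error only, so the calls among unchanged genes leave out any variation between cultures. In PC3 against LNCAP 100% of genes made 8-fold higher and 100% of those made 8-fold lower were called, with 4 calls among unchanged genes of 16368 tested. In DU145 against LNCAP these shares were 100% and 98%, with 3 such calls of 16403 tested. In PC3 against DU145 both were 100%, with 7 such calls of 16379 tested. At an assumed coefficient of variation of 0.4, unchanged libraries gave more calls, with 85.8 genes higher and 19.4 lower in both lines against LNCAP. Of 200 random lists of 20 genes without a shift in PC3 against LNCAP, 7.5% stood apart, and 99.5% did so with a log2 shift of 2. The edgeR fit was tested on simulated data at a coefficient of variation of 0.4, where it recovered 60% of genes changed 8-fold and 100% of those changed 64-fold, with 4 false calls among 15893 genes tested. At the coefficient of 0.77 fitted to these libraries it recovered 0% of either, among 16216 genes tested.

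Alternatives covered other scalings (DESeq2 size factors, upper quartile, total counts), no filter and a filter of 5 CPM, 5 added counts, the authors' FPKM on the log2 scale with 0.1 or 1 added, thinning to the smallest library, protein-coding genes only, thresholds of 2-fold and 8-fold, list means, and other ways of matching random lists. Removing mitochondrial genes from the genes compared and from the library totals, with the TMM factors kept, was added after seeing the data. Figures were drawn with matplotlib 3.10.9.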

Results

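Gene expression was measured by RNA sequencing in 3 human prostate cancer cell lines, with 1 library per line. LNCAP, a line from a lymph node metastasis that responds to androgen, stood for androgen-dependent cancer in the series design. PC3 and DU145, lines from a bone and a brain metastasis that grow without androgen, stood for castration-resistant cancer, which progresses despite androgen deprivation. The libraries held 15393103 counts in LNCAP, 15319045 in PC3 and 15878546 in DU145. Of 58735 annotated genes, 26399, 25191 and 25288 had at least 1 count. Mitochondrial genes took 7.97% of the counts in LNCAP, 4.35% in PC3 and 5.6% in DU145. A count of 0 allowed up to 3 counts, which is 0.195, 0.196 and 0.189 CPM of the unscaled totals in the same order. The bounds on folds used the TMM-scaled totals instead. There were no replicates, so no difference has a replicate check. Coordinates are on GRCh38.

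Genes that tell the lines apart were read first. KLK3, which encodes prostate-specific antigen, stood at 2271 normalised CPM in LNCAP and had no counts in either other line. PC3 was lowest in CTNNA1, which encodes the adhesion protein alpha-catenin (362, 2.16 and 506 CPM in LNCAP, PC3 and DU145). LNCAP was lowest in CDKN2A (18.9, 96.8 and 427 CPM), a locus that encodes cell cycle inhibitors. RB1 stood at 60.6, 42.85 and 63.1 CPM, and ERG was under 1 CPM in each library.

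The comparison of PC3 with LNCAP asked how a castration-resistant line differed from the androgen-dependent one. Androgen response genes were lower in PC3, where 20 of 28 measured members were at least 4-fold lower and 1 was higher. KLK3 was at least 11570-fold lower, and its neighbour KLK2 at least 1825-fold lower. ALDH1A3, an aldehyde dehydrogenase gene, went against the list at 10.3-fold higher (95% counting interval 9.76 to 10.8). Mesenchymal genes were higher, with 17 of 24 members at least 4-fold higher and 2 lower. Among them CDH11, a cadherin gene, was at least 2691-fold higher, and CDH2, which encodes N-cadherin, was 3456-fold higher from 1 LNCAP count (620 to 136500). The matrix protein gene FN1 went against this list at 13.4-fold lower in PC3 (13.0 to 13.7), from 5033 CPM in LNCAP to 377 CPM. TGFBI, a matrix protein gene, was the other member lower, at 7.82-fold from 1 PC3 count (1.05 to 347).

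Epithelial junction genes were lower in PC3, with 17 of 24 members at least 4-fold lower and none higher. The E-cadherin gene CDH1 was 353-fold lower (253 to 510), the membrane protease gene ST14 1128-fold lower (440 to 4142) and the splicing regulator gene ESRP1 356-fold lower (121.5 to 1728). Proteases and their inhibitors were higher, with 14 of 19 members at least 4-fold higher and only MMP7 lower. PLAT, which encodes tissue plasminogen activator, was 1624-fold higher (1073 to 2592) and the urokinase gene PLAU 524-fold higher (312 to 960). Basal epithelium markers were higher for 8 of 14 members, such as CD44 at least 1440-fold and ITGB4 91.4-fold (71.1 to 120), but the keratin genes KRT14 and KRT6A were at least 29-fold and at least 5.21-fold lower. The list of YAP and AP-1 targets also holds genes of these factors themselves, which respond to adhesion and growth signals. Of its members 11 of 22 were higher, and FOSL1, an AP-1 factor gene, was 1030-fold higher (522 to 2386). In the list of NF-kB and cytokine genes 10 of 22 members were higher, including CXCL1 at least 183-fold, and 4 were lower, including BIRC3 at 14.4-fold (12.3 to 17.1).

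Steroid metabolism genes were lower in PC3 for 10 of 17 members, none of them higher. The glucuronidation genes UGT2B11 and UGT2B17 were at least 195-fold and at least 180-fold lower, with reads that near copies could share. Luminal markers were lower for 7 of 14 members, among them FOLH1, the gene of prostate-specific membrane antigen, at 6158-fold from 2 PC3 counts (1704 to 50860). KRT19 went against that list at 17.5-fold higher (15.8 to 19.5). Growth factor receptors and surface antigens were lower for 11 of 21 members, such as STEAP2 at 47.8-fold (42.5 to 54.0), and higher for 5. Among these 5, MET was 397-fold higher (275 to 598) and AXL 7447-fold higher from 1 LNCAP count (1336 to 294200). Of 12 cancer-testis antigens 10 were lower and none was higher, with MAGEA3 10.1-fold lower (8.89 to 11.6). Sterol and fatty acid synthesis genes were lower for 5 of 24 members and higher for none.

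In PC3 against LNCAP, 2344 of the 18025 tested genes were at least 4-fold higher and 2402 lower, which is 26.3% of them. The median log2 ratio was -3.70 for androgen response, -3.81 for steroid metabolism, -1.71 for luminal markers, -3.19 for epithelial junctions and -1.21 for sterol synthesis, each at percentile 0 of the matched random lists. It was -2.30 for growth factor receptors and surface antigens and -5.83 for cancer-testis antigens, also at percentile 0. It was 5.55 for mesenchymal genes, 5.41 for proteases, 2.92 for basal markers and 2.38 for YAP and AP-1 targets, each at percentile 100. With members lacking counts at their bound, the medians became -3.18 for steroid metabolism, -3.38 for cancer-testis antigens, 4.96 for mesenchymal genes and 4.00 for proteases. NF-kB and cytokine genes had a median of 1.08 (percentile 99.8), 1.05 with bounds, and did not stand apart with 1 added to FPKM (0.29, percentile 94.3). Cell cycle genes had a median of 0.57 (percentile 99.3), with TOP2A 4.69-fold higher (4.47 to 4.92) and CCNE1 14.2-fold lower (9.81 to 21.3) of 28 members, and did not stand apart by their mean (0.40, percentile 85.0) or with unmatched lists (percentile 97.25). Of 20 antigen presentation genes 5 were lower in PC3, including HLA-B at 7.67-fold (5.84 to 10.2), and PSMB8 was 27-fold higher (15.25 to 52.9). Antigen presentation had a median of -0.72 (percentile 1.75), and this list did not stand apart without its HLA genes (-0.45, percentile 12.5), with a 5 CPM filter (-0.45), with 5 added counts (-0.63), on FPKM with 0.1 or 1 added (-0.56 and -0.31), by its mean (-0.64) or with unmatched lists (percentile 2.93).

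The other lists described here did not stand apart in PC3 against LNCAP. Their medians were -0.43 for neuroendocrine genes (-0.45 with bounds), -0.26 for interferon response and -0.28 for hypoxia and glycolysis. They were -0.48 for NRF2 and glutathione genes, -0.02 for DNA repair, -0.04 for housekeeping genes and -0.05 for stromal, endothelial and immune markers (mean 0.98). Of that last list 9 genes reached 1 CPM in any library, among them COL1A1 at 33.1, 31.9 and 9.45 CPM in LNCAP, PC3 and DU145. Neuroendocrine genes stood apart with a 5 CPM filter (-2.39, percentile 1.78), and NRF2 and glutathione genes with 1 added to FPKM (-0.44, percentile 1.76). ALDOA, a glycolysis gene, was read at 6.72, 7.33 and 7.28 CPM; it lies almost wholly inside another gene model on the same strand, and its value is uncertain.

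Genes apart from LNCAP in PC3 and less than 2-fold apart in DU145 included FBN2, a fibrillin gene, at least 2530-fold higher in PC3. FBN2 had no counts in LNCAP or DU145, so no fold between those lines was measured. SHISA3 was 2534-fold higher (701 to 20930) and ONECUT3 1761-fold higher (487 to 14550), each from 2 LNCAP counts. With so few reads, their distance between LNCAP and DU145 is uncertain. In the other direction STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568), which encodes a transcription factor of cytokine signalling, had no counts in PC3 and 4525 in LNCAP, at least 1475-fold lower. The acetyltransferase gene KAT2A (chromosome 17, 42113108 to 42121358) was at least 712-fold lower, and RAB5C (chromosome 17, 42124976 to 42155044) at least 308-fold. TSPAN14 on chromosome 10 was at least 499-fold lower and DAPK1 on chromosome 9 at least 277-fold lower. The 22 gene models annotated from KAT2A to ATP6V0A1 on chromosome 17 (42113108 to 42522611) had 3 counts in PC3, 9942 in LNCAP and 31342 in DU145. The next genes on either side in the map of this region, NKIRAS2 and NAGLU, had 516 and 212 counts in PC3.

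**Figure D1:**
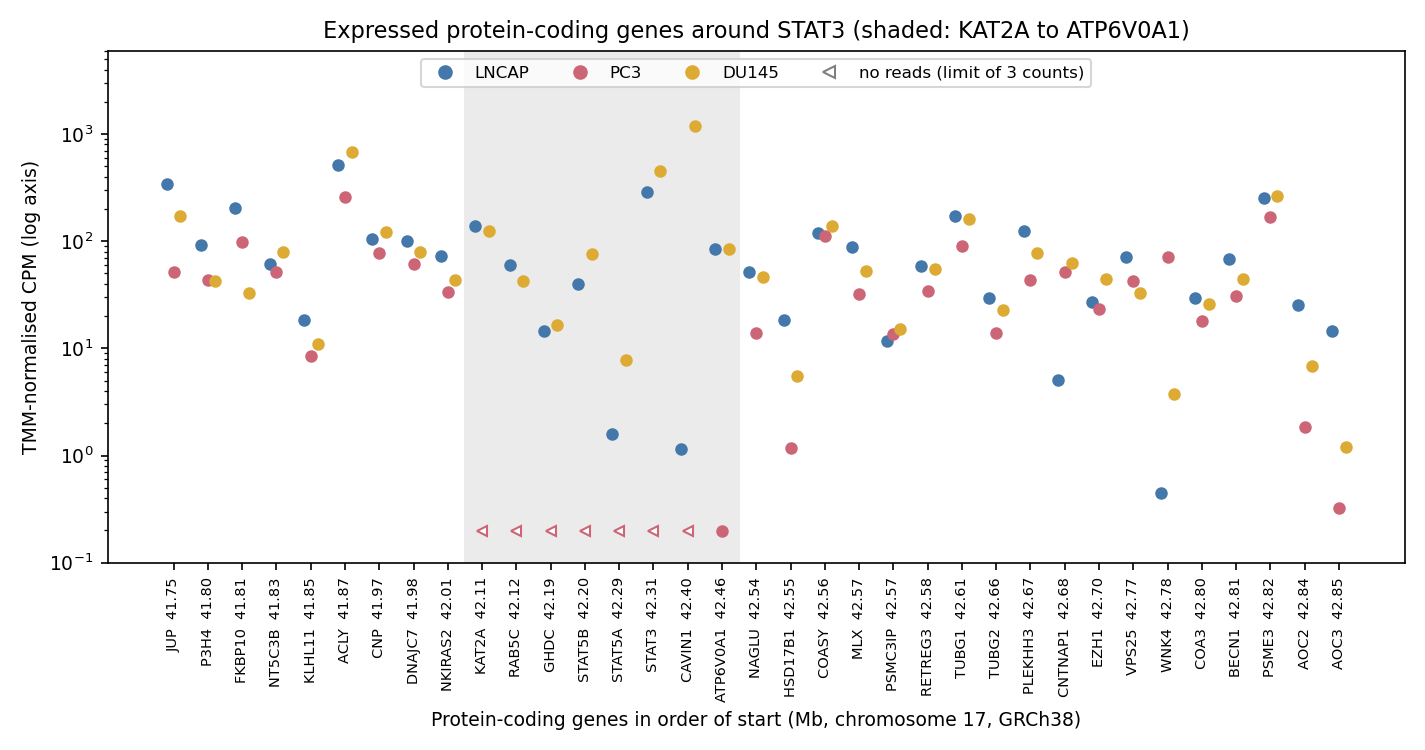
Normalised CPM (log axis) of expressed protein-coding genes around STAT3 on chromosome 17, in order of start position (Mb, GRCh38), with 1 point per line and open triangles at the limit of 3 counts where a line had no reads. In the shaded interval PC3 had no reads for 7 genes and 3 reads for ATP6V0A1, while genes on both sides had PC3 reads.

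The comparison of DU145 with LNCAP asked the same of the second castration-resistant line. Androgen response genes were lower, with 21 of 28 members at least 4-fold lower and none higher. KLK3 was at least 11860-fold lower, TMPRSS2, a membrane protease gene, at least 4064-fold lower and ADAMTS1 at least 4015-fold lower. Luminal markers were lower for 8 of 14 members, with FOLH1 at least 4209-fold lower and the homeobox gene HOXB13 at least 1717-fold lower, whereas CD24 was 25.9-fold higher (23.3 to 29) and KRT19 17.1-fold higher (15.4 to 19.0). Basal markers were higher for 9 of 14 members, such as CAV1 at least 2294-fold, while KRT14 was at least 29.7-fold lower and KRT6A 8.02-fold lower from 2 DU145 counts (1.89 to 71.9). Mesenchymal genes were higher for 15 of 24 members, with the vimentin gene VIM 146-fold higher (111.5 to 194), but FN1 was 150-fold lower (138 to 164) and TWIST1 at least 477-fold lower.

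YAP and AP-1 targets were higher in DU145 for 15 of 22 members and lower for none, with NT5E, which encodes the ectoenzyme CD73, at least 1443-fold higher. Among NF-kB and cytokine genes 12 of 22 were higher, including ICAM1 at 66.5-fold (49.1 to 92.5) and TNFAIP2 at 42.5-fold (34.9 to 52.2), and 3 were lower, including CCL2 at 13.5-fold from 2 DU145 counts (3.40 to 117). Proteases were higher for 7 of 19 members, with PLAU 841-fold higher (501 to 1538), while MMP7 was at least 30.1-fold lower and MMP13 13.7-fold lower from 3 DU145 counts (4.37 to 69.2). NRF2 and glutathione genes were higher for 8 of 22 members, and AKR1C1 was 6.27-fold lower (4.95 to 8.03). AKR1B1, an aldose reductase gene, was 720-fold higher (349 to 1791), GSTP1, a glutathione transferase gene, at least 339-fold higher and NQO1 7.27-fold higher (6.97 to 7.59). Antigen presentation genes were higher for 5 of 20 members and lower for none, with PSMB8, an immunoproteasome gene, 47.4-fold higher (26.9 to 92.3) and the peptidase gene ERAP2 26.2-fold higher (19.9 to 35.1). Of 28 cell cycle genes 2 were at least 4-fold higher, TOP2A at 6.71-fold (6.41 to 7.03) and AURKA at 4.11-fold (3.78 to 4.48), and 26 were under 4-fold.

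Steroid metabolism genes were lower in DU145 for 9 of 17 members, and AKR1C3 was 9.53-fold higher (6.49 to 14.5), with reads that its near copies could share. Epithelial junction genes were lower for 10 of 24 members, with the transcription factor gene GRHL2 at least 1405-fold lower and RAB25 281-fold lower from 3 DU145 counts (95.8 to 1365). Cancer-testis antigens were lower for 9 of 12 members, such as MAGEA3 at least 872-fold, but XAGE1B was at least 6.32-fold higher and BRDT 16.7-fold higher (11.4 to 25.4). Growth factor receptors and surface antigens went both ways, with 7 of 21 members higher and 7 lower. AXL was 14460-fold higher from 1 LNCAP count (2595 to 571200). Hypoxia and glycolysis genes were higher for 4 of 23 members, including VEGFA at 5.35-fold (5.03 to 5.69), and lower for 5, including CA12 at 40.9-fold (29.4 to 58.6).

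In DU145 against LNCAP, 2473 of 18025 tested genes were at least 4-fold higher and 2178 lower, together 25.8%. Median log2 ratios were -3.19 for androgen response, -2.53 for steroid metabolism, -4.93 for luminal markers, -1.79 for epithelial junctions and -7.31 for cancer-testis antigens, each at percentile 0, and the last was -5.97 with bounds. They were 4.30 for basal markers, 4.07 for mesenchymal genes (3.56 with bounds), 3.32 for YAP and AP-1 targets, 3.16 for NF-kB and cytokine genes (2.5 with bounds) and 1.11 for cell cycle genes, each at percentile 100. Proteases had a median of 1.45 (percentile 99.96), antigen presentation 1.24 (99.91) and NRF2 and glutathione genes 0.94 (99.89). The lists that did not stand apart were neuroendocrine genes (1.43; 1.15 with bounds), interferon response (-0.60), hypoxia and glycolysis (-0.43), sterol synthesis (0.46), DNA repair (0.19), growth factor receptors and surface antigens (-0.45; -0.17 with bounds), housekeeping genes (0.19) and stromal, endothelial and immune markers (-1.48). Of these, hypoxia genes stood apart without a filter (-0.46), growth factor receptors without a filter (-1.03), and neuroendocrine genes and stromal markers against unmatched lists (percentiles 98.3 and 0.93).

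Genes apart from LNCAP in DU145 and under 2-fold apart in PC3 included FAM83A, which was 1220-fold higher (592 to 3036), and the non-coding RNA LINC00707, at least 772-fold higher. LINC00707 had no counts in LNCAP or PC3, so no fold between those lines was measured. The potassium channel gene KCNQ3 was at least 593-fold higher, BCAT1, an amino acid transaminase gene, 535-fold higher (299 to 1072) and the vitamin D hydroxylase gene CYP24A1 at least 363-fold higher. KCNQ3 and CYP24A1 likewise had no counts in LNCAP or PC3. HOXB13 (chromosome 17, 48724763 to 48729178) and its neighbour PRAC1 (chromosome 17, 48721719 to 48722522) had no counts in DU145, and PRAC1 was at least 90.5-fold lower. DSEL was 842-fold lower from 1 DU145 count (151 to 33290), the ephrin receptor gene EPHA7 at least 87.2-fold lower and CCDC141 at least 83.9-fold lower.

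**Figure D2:**
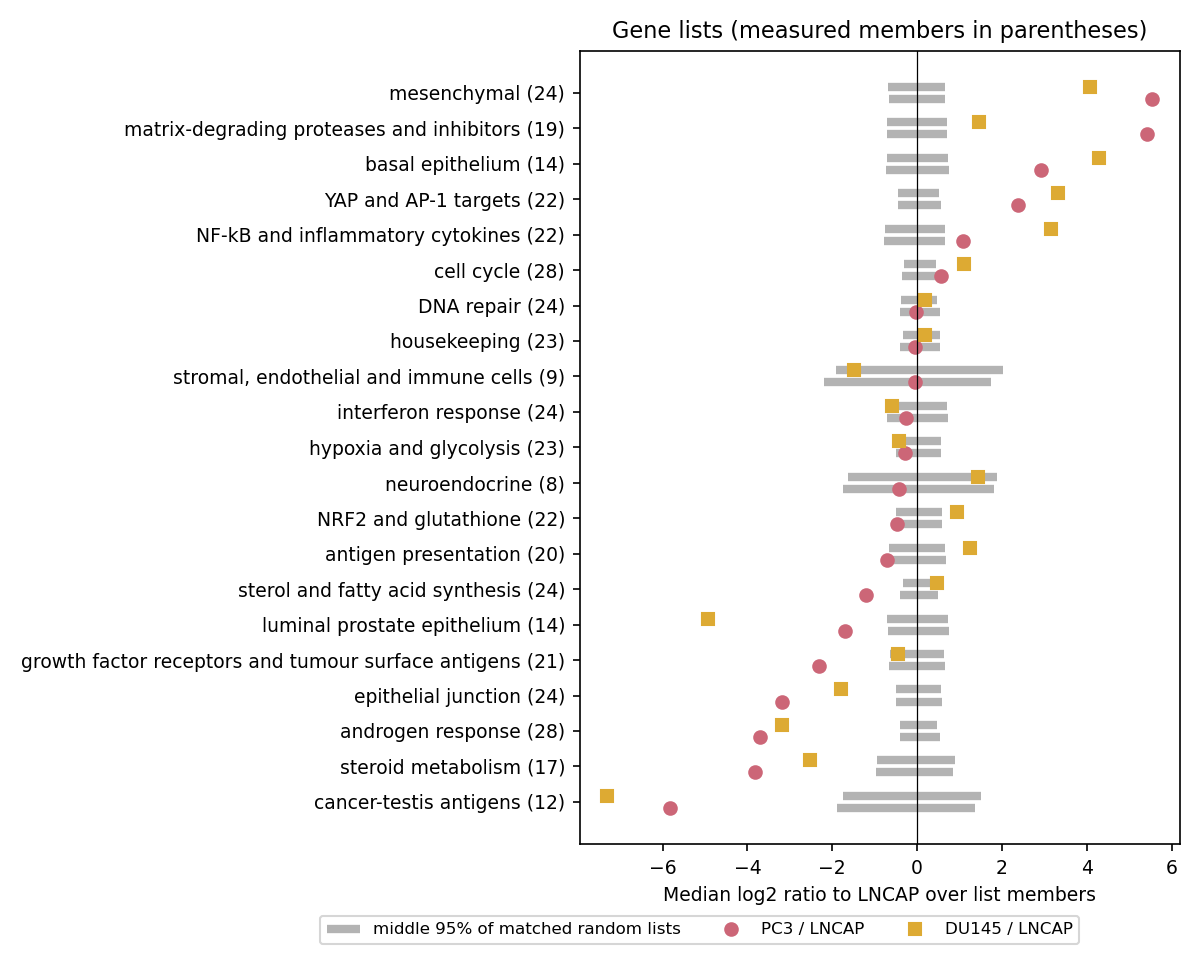
Median log2 ratio to LNCAP over the measured members of each gene list described here, as circles for PC3 and squares for DU145, with grey bars for the middle 95% of 10000 matched random lists. Androgen response lay at -3.70 and -3.19 and mesenchymal genes at 5.55 and 4.07, and antigen presentation lay on opposite sides of 0.

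The class comparison asked which genes separated both castration-resistant lines from LNCAP in the same direction. S100A6 (ENSG00000197956, chromosome 1, 153534599 to 153536244), which encodes a calcium-binding protein, had no counts in LNCAP and stood at 630.1 CPM in PC3 and 637 CPM in DU145, at least 3283-fold and at least 3320-fold higher. ANXA2 (chromosome 15, 60347134 to 60402883), the annexin A2 gene, was 3686-fold (1789 to 9168) and 3109-fold higher (1509 to 7734). IGFBP4 (chromosome 17, 40443461 to 40457731), a growth factor binding protein gene, was at least 14940-fold and at least 1284-fold higher, and DKK1 (chromosome 10, 52314296 to 52318042), which encodes a secreted Wnt inhibitor, at least 13370-fold and at least 735-fold. CAV1 (chromosome 7, 116524785 to 116561184), a caveolin gene, was at least 1242-fold and at least 2294-fold higher, and CD44 (chromosome 11, 35138870 to 35232402) at least 1440-fold and at least 733-fold. EDIL3 (chromosome 5, 83940554 to 84384793) was at least 651-fold higher in PC3 and at least 2345-fold in DU145. The growth factor gene AREG (chromosome 4, 74445134 to 74455009) was at least 972-fold and at least 535-fold higher. LGALS1 (chromosome 22, 37675608 to 37679806), a galectin gene, stood at 0.256 CPM in LNCAP, 299.6 CPM in PC3 and 356 CPM in DU145. AXL (chromosome 19, 41219203 to 41261766), which encodes a receptor tyrosine kinase, stood at 0.064 CPM in LNCAP, 476 CPM in PC3 and 925 CPM in DU145.

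Among genes lower in both lines, KLK3 (ENSG00000142515, chromosome 19, 50854915 to 50860764) and KLK2 (chromosome 19, 50861568 to 50880567) had no counts in PC3 or DU145. SYT4 (chromosome 18, 43267878 to 43277650), a synaptotagmin gene, stood at 458 CPM in LNCAP and GPR158 (chromosome 10, 25174802 to 25602226), an orphan receptor gene, at 440.3 CPM, and neither had counts in the other lines. FOLH1 (chromosome 11, 49146635 to 49208670) stood at 806 CPM in LNCAP, 0.131 CPM in PC3 and no counts in DU145. The transcription factor gene MAF (chromosome 16, 79585843 to 79600714) was at least 916-fold and at least 938-fold lower. PEG3 (chromosome 19, 56810077 to 56840728), an imprinted gene, was 1687-fold lower in PC3 (723 to 5198) and 4324-fold lower in DU145 from 2 counts (1197 to 35710). The potassium channel gene KCNN2 (chromosome 5, 114055545 to 114496500) was at least 738-fold and at least 756-fold lower, and the defensin gene DEFB132 (chromosome 20, 257736 to 261096) at least 699-fold and at least 716-fold.

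**Figure D3:**
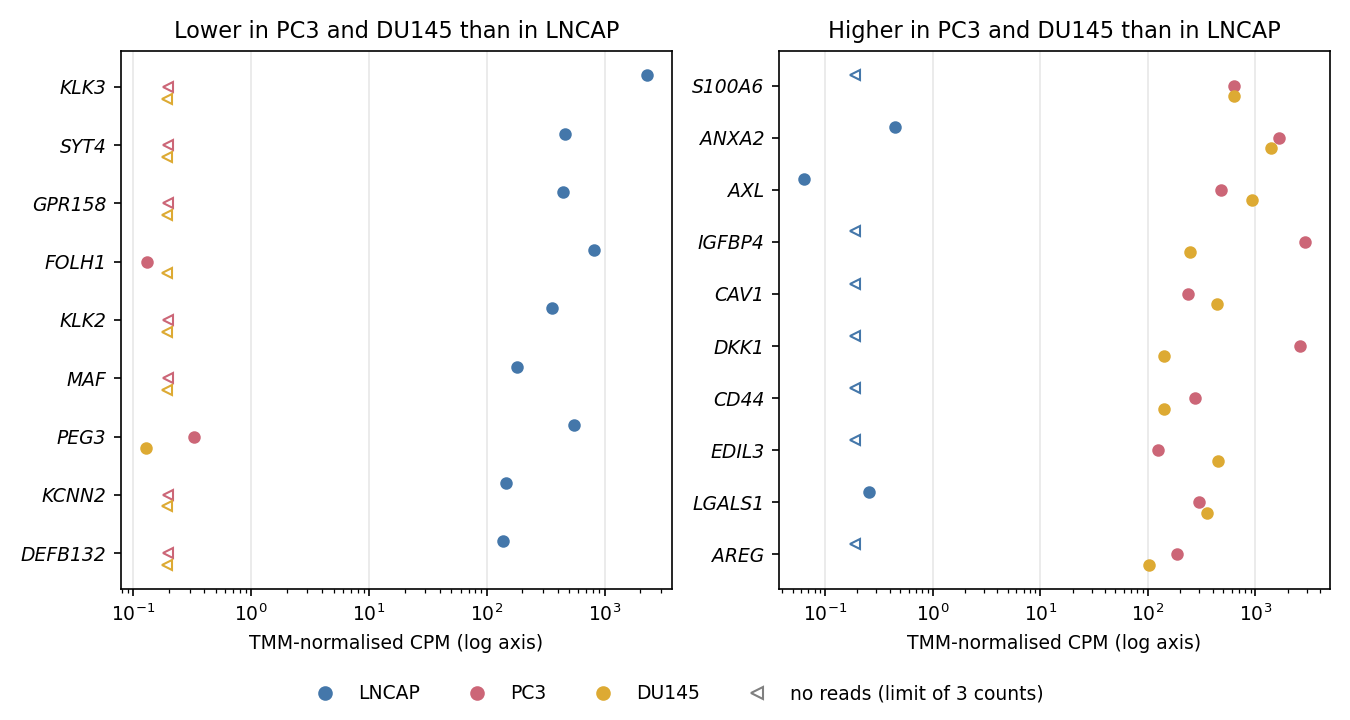
Normalised CPM (log axis) of the named genes lower and the 10 named genes higher in both PC3 and DU145 than in LNCAP, with 1 point per line and open triangles at the limit of 3 counts where a line had no reads. KLK3 lay at 2271 CPM in LNCAP with no reads in the other lines, and S100A6 had no reads in LNCAP.

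By list, 18 of 28 androgen response genes were lower in both lines and none was higher in both, and 9 of 17 steroid metabolism genes were lower in both. Mesenchymal genes were higher in both for 13 of 24 members, among them VIM, ZEB1, AXL and COL4A1, and FN1 was lower in both. Basal markers were higher in both for 7 of 14, YAP and AP-1 targets for 11 of 22, proteases for 7 of 19 and NF-kB and cytokine genes for 9 of 22. Members of these lists lower in both were KRT14 and KRT6A (basal), MMP7 (proteases), and CCL2 and CCL20 (cytokines). The epithelial junction list also holds regulators, such as GRHL2 and ESRP1, and 9 of its 24 members were lower in both. These were CDH1, CLDN7, ESRP1, GRHL2, OVOL1, OVOL2, RAB25, ST14 and SPINT1. Other members, such as CTNNA1, JUP and TJP1, were not 4-fold lower in both. Cancer-testis antigens were lower in both for 9 of 12. The transcription factor gene GATA2 was lower in both, and GATA3 and the glucocorticoid receptor gene NR3C1 were higher in both. No housekeeping gene of 23 was 4-fold apart from LNCAP in either line.

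In all, 1363 genes were at least 4-fold higher than LNCAP in both lines and 1354 were lower in both, of which 1069 and 869 were protein-coding. Independent lists of these sizes would share 321.6 and 290.2 genes. Simulated unchanged libraries that shared the LNCAP library gave 2.3 and 0.2 genes with Poisson counts, and 85.8 and 19.4 at an assumed coefficient of variation of 0.4. A further 81 genes were higher in PC3 and lower in DU145, and 65 the reverse. Across genes, which are not independent replicates, the log2 ratios of both lines to LNCAP had a correlation of 0.663 and a covariance of 5.09, beside 0.502 and 0.045 for simulated Poisson counts and 0.501 and 0.414 with the assumed variation. The covariance thus exceeded the simulated values by 5.05 and 4.68. The LNCAP library could not be split, so part of the excess may come from the shared library. The assumed 0.4 is also below the 0.77 that edgeR fitted to these libraries, and unchanged libraries were not simulated at that value. Larger variation would raise the simulated counts and covariance, so the excess may be overstated. With PC3 as the shared library, 817 genes were higher and 823 lower in both others. Independent lists would share 254.4 and 200.1 genes there, and simulation with the assumed variation gave 92.1 and 18.2. The correlation was 0.436, below the simulated 0.505 and 0.502, and the covariance 2.79, above the simulated 0.046 and 0.418. With DU145 shared these were 565 and 947 genes, beside 186.0 and 261.9 for independent lists and 83 and 22.4 with the assumed variation. The correlation was then 0.384 beside 0.497 and 0.50, and the covariance 2.40 beside 0.044 and 0.416. An overlap above the independent value was thus seen with each shared library and is not particular to LNCAP. With edgeR's quasi-likelihood test of both lines against LNCAP, 0 of 18025 genes passed an adjusted p of 0.05 (smallest adjusted p 0.266), 1746 had an unadjusted p under 0.05, limma-voom also called 0, and DESeq2 called 1306, of which 912 were higher and 394 lower. At the coefficient of variation of 0.77 fitted here, the edgeR test recovered 0% of simulated 64-fold changes.

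**Figure D4:**
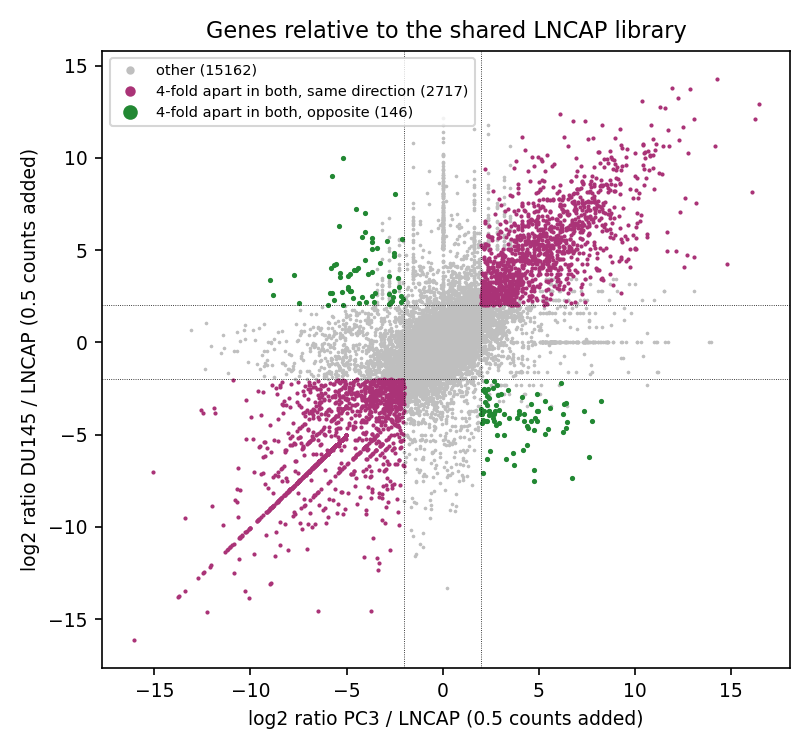
Log2 ratio to LNCAP of each tested gene in PC3 (horizontal axis) and DU145 (vertical axis), with 0.5 counts added; purple points were 4-fold apart in the same direction in both lines and green points in opposite directions. The purple points hold 1363 genes higher and 1354 lower in both lines, and the shared LNCAP library places both axes on a common reference.

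The comparison of PC3 with DU145 asked how far lines of the same class differed. RELN, which encodes the extracellular protein reelin, was at least 2882-fold higher in PC3, CDH11 at least 2697-fold, FBN2 at least 2536-fold and the receptor gene ADGRF1 at least 2413-fold. HOXB13 was at least 2019-fold higher in PC3, the collagen gene COL6A3 at least 1332-fold and PLCXD3 at least 1195-fold, and SULF2, a sulfatase gene, was 3446-fold higher from 2 DU145 counts (954 to 28460). In the other direction CAVIN1, which encodes a coat protein of caveolae, was at least 6066-fold higher in DU145 and UCHL1, a deubiquitinase gene, at least 4564-fold. STAT3 was at least 2310-fold higher in DU145, KAT2A at least 632-fold, the transcription factor gene NKX2-1 at least 886-fold, the phospholipid transporter gene ATP10A at least 885-fold and LINC00707 at least 755-fold. FAM83A was 1193-fold higher in DU145 (579 to 2969). CAVIN1, STAT3 and KAT2A all lie in the interval of chromosome 17 that had 3 counts in PC3.

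Antigen presentation genes were lower in PC3 than in DU145 for 10 of 20 members and higher for none, with HLA-B 28.2-fold lower (21.8 to 37.2), ERAP2 11.8-fold lower (9.74 to 14.4) and PSMB9 16.5-fold lower (9.83 to 29.95). Epithelial junction genes were lower for 10 of 24, with CTNNA1 234.5-fold lower (167 to 341) and CDH1 65.1-fold lower (46.5 to 94.2), and GRHL2 was at least 2.73-fold higher from 8 PC3 counts. Sterol synthesis genes were lower in PC3 for 6 of 24, led by FDFT1 at 8.97-fold (8.25 to 9.77). NRF2 and glutathione genes were lower for 5 of 22, including AKR1B1 at 145-fold (104 to 209.5) and NQO1 at 17-fold (16 to 18.1). Growth factor receptors and surface antigens were lower for 6 of 21 and higher for 2. Proteases were higher in PC3 for 6 of 19, with PLAT 1156-fold higher (814 to 1701), while CTSL was 9.24-fold lower (8.35 to 10.25) and ADAM9 4.05-fold lower (3.90 to 4.21). Mesenchymal genes went both ways, with 6 of 24 higher, such as CDH2 at least 1155-fold, and 5 lower, such as TGFBI at 2168-fold from 1 PC3 count (389 to 85650).

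In PC3 against DU145, 1539 of 18025 genes were at least 4-fold higher and 1909 lower, together 19.1%, fewer than in either comparison with LNCAP. Median log2 ratios were -1.81 for antigen presentation (-1.47 with bounds), -1.44 for epithelial junctions, -1.27 for sterol synthesis and -1.48 for NRF2 and glutathione genes, at percentiles of 0.01 or lower. They were -0.53 for cell cycle genes (percentile 0.23), -0.94 for NF-kB and cytokine genes (0.13; -0.65 with bounds), -0.87 for growth factor receptors and surface antigens (0.18) and 0.72 for mesenchymal genes (99.0). Proteases had a median of 1.14 (99.99), which did not stand apart with a 5 CPM filter (0.22). Calls that several alternatives ended were those of basal markers (-0.80, percentile 0.63; -0.36 with bounds; -0.58 with 5 added counts), DNA repair (-0.38, percentile 2.23; -0.31 without a filter) and stromal, endothelial and immune markers (1.62, percentile 98.3; 0.00 with bounds; 0.04 without a filter). YAP and AP-1 targets (-0.56, percentile 0.67) did not stand apart against unmatched lists (percentile 2.93), nor did the means of NF-kB and cytokine genes (-0.66) and of growth factor receptors and surface antigens (-0.91). The lists that did not stand apart were androgen response (0.24; 0.11 with bounds), steroid metabolism (-0.30), luminal markers (0.04; 0.00 with bounds), neuroendocrine genes (-0.20; -0.22 with bounds), interferon response (0.07), hypoxia and glycolysis (-0.02), cancer-testis antigens (0.04, and 0.00 with bounds) and housekeeping genes (-0.30). Of 12 cancer-testis antigens 11 had no counts in PC3, DU145 or both, so their median says little, and 3 were higher and 2 lower in PC3. By their means, androgen response (0.88), luminal markers (1.93) and neuroendocrine genes (-2.07) stood apart. Over the 3 pairs of lines, which share libraries, 41 of 66 list comparisons stood apart, where the nominal 5% is 3.3. In PC3 against LNCAP 7.5% of random lists without a shift stood apart.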

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

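The test of the HLA genes between PC3 and DU145 was written before the result was seen; the tests of random placement, of the whole interval, of library depth, of the HLA genes in each comparison with LNCAP, of scaling, of the mitochondrial share, of culture medium and of class were chosen after.

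In PC3, 69 of 9607 protein-coding genes at 5 CPM or more in both other lines had 3 counts or fewer, and 9 pairs of them were neighbours; of 10000 random placements, as a test of genes lost one by one independent of position, 0 gave as many (mean 0.48, highest 6). The run from KAT2A to ATP6V0A1 on chromosome 17 had been noticed among the named genes beforehand, and without it 4 pairs were left, which 17 placements reached. Low depth is argued against, since the PC3 total was 99.5% of the smaller total of the other libraries. A deletion of the whole interval stays open: its 15 other annotated genes, leaving out CAVIN1 and the 6 that define it, had 0 PC3 reads where 136.2 were expected (upper limit 2.2%), but the 3 reads seen before over all 22 genes had already fixed this, and the limit of 10% was set afterwards. Silencing across the interval would give the same counts, DNA was not analysed here, and no biological explanation from the design was tested.

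The antigen presentation list lay below LNCAP in PC3 (median log2 -0.72) and above it in DU145 (1.24), an opposite direction in lines of the same class that was not itself tested with replicates. Reads shared among HLA genes are argued against for PC3 against DU145 and for DU145 against LNCAP, where without the 7 HLA genes the medians of -1.39 and 1.11 lay at percentiles 0.03 and 99.23. For PC3 against LNCAP the call ended without them, from -0.72 at percentile 1.75 to -0.45 at percentile 12.52 over 13 genes, so shared reads and a shorter list cannot be told apart there. Scaling between libraries would move all genes alike; the list median minus the housekeeping median, with members of both lists resampled for a 95% interval, argues against it for PC3 against DU145 (-1.51, -3.27 to -0.46) and DU145 against LNCAP (1.05, 0.10 to 1.70), but leaves it open for PC3 against LNCAP (-0.67, -1.60 to 0.08). Different culture media of the lines stay open, since each line has 1 library, and so does an untested biological difference between the lines.

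The number of genes 4-fold apart was larger in either comparison with LNCAP than between PC3 and DU145, with the smaller LNCAP count 1.35 times the other. A higher mitochondrial share in LNCAP is argued against as a shift in scaling: the shares could move log2 ratios by at most 0.056, and on total counts, with the thresholds moved that far against the pattern, the ratio was still 1.28. Whether that share marks another difference of the library was not tested. Library depth is argued against, since the LNCAP total, 98.7% of the mean of the others, lay between them. The androgen-dependent against castration-resistant class cannot be told apart from LNCAP as a line, since 1 library stands for the androgen-dependent class.

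Several named genes were called 4-fold above LNCAP in PC3 or DU145 and 4-fold below it in the other line, and these differences were not tested. Those higher in PC3 than in DU145 were RELN (at least 2882-fold), ADGRF1 (at least 2413-fold), SULF2 (3446-fold, 954 to 28460), MMP13 (661-fold, 226 to 3207), COL3A1 (122.5-fold, 33.5 to 1017), IFI44L (75.9-fold, 13.2 to 3036) and IL1B (at least 26.3-fold). Those higher in DU145 than in PC3 were CAVIN1 (at least 6066-fold), UCHL1 (at least 4564-fold), TGFBI (2168-fold, 389 to 85650), ATP10A (at least 885-fold) and BRDT (at least 152.5-fold). These folds compare PC3 with DU145, and the distance of either line from LNCAP can be much smaller. CAVIN1 had 18 counts in LNCAP, 0 in PC3 and 18656 in DU145. The PC3 count of TGFBI was below the floor of 3 counts, so its place below LNCAP rests on few reads. The places of IFI44L, COL3A1, SULF2 and MMP13 below LNCAP likewise rest on few DU145 reads, which their wide intervals reflect.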

How the results depend on the processing

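Of the alternatives, only the removal of mitochondrial genes, with the TMM factors kept, was chosen after seeing the data. No list median that stood apart turned its direction under any alternative run. Over all alternatives, 76 gene counts stayed within 1.5 times the reported value and 28 did not, and 818 list results kept their side of the threshold, 29 lost the call and 11 gained it. The other scalings, thinning and the removal of mitochondrial genes moved no count by more than 1.5 times, but thinning removed at most 3.52% of a library and the other scalings moved the median log2 ratio of all genes no further than -0.09, so they test little. No paired analysis was possible because each line has 1 library, and leaving out a library would leave 1 against 1, with no residual degrees of freedom and no test. Depth limits genes near the floor of 3 counts.

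Fewer genes pass a stricter filter, a higher threshold or a larger added value by construction, and more pass a lower threshold. With a 5 CPM filter the counts were 1327 lower in PC3 against LNCAP, 1624 higher and 1198 lower in DU145 against LNCAP, 943 higher and 1104 lower in PC3 against DU145, and 722 lower in both. With 1 added to FPKM they were 908 and 746, 887 and 665, and 474 and 523 in the same order of pairs, and 391 and 456 in both. At 2-fold they were 4076 and 4247, 4119 and 4169, 3336 and 3479, and 2306 and 2610. At 8-fold 1424 genes were lower in DU145 against LNCAP, 925 higher and 1234 lower in PC3 against DU145, and 875 lower in both. Among protein-coding genes 1412 were lower in DU145 against LNCAP and 869 in both. The edgeR count of 0 (1746 at an unadjusted p under 0.05) was also 0 in the other edgeR fits and with limma-voom, and 1306 with the DESeq2 Wald test; since the edgeR fit recovered 0% of simulated 64-fold changes at the fitted coefficient of variation of 0.77, a count of 0 says nothing about stability.

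For the lists the cause was not tested, and values are median log2 ratios unless stated. PC3 against LNCAP lost the call for antigen presentation with a 5 CPM filter (-0.45), 5 added counts (-0.63), FPKM with 0.1 or 1 added (-0.56, -0.31), the mean (-0.64) and unmatched lists (-0.72), for NF-kB and cytokine genes with 1 added to FPKM (0.29), and for cell cycle by the mean (0.40) and unmatched lists (0.57). It gained neuroendocrine genes with a 5 CPM filter (-2.39) and NRF2 genes with 1 added to FPKM (-0.44). DU145 against LNCAP gained hypoxia genes without a filter (-0.46) and among protein-coding genes (-0.43), growth factor receptors without a filter (-1.03), a list not described here by the mean (-1.60), and neuroendocrine genes (1.43) and stromal markers (-1.48) with unmatched lists. PC3 against DU145 lost DNA repair without a filter (-0.31), with a 5 CPM filter, 5 added counts, FPKM with 0.1 added, protein-coding genes and unmatched lists (-0.38 each) and by the mean (-0.37). It lost stromal markers without a filter (0.04), with 5 added counts (0.30), FPKM with 0.1 or 1 added (0.09, 0.01), the mean (1.78) and length matching (1.62). It lost basal markers with 5 added counts (-0.58), 1 added to FPKM (-0.37) and the mean (-0.53), proteases with a 5 CPM filter (0.22), YAP and AP-1 targets with unmatched lists (-0.56), and by the mean NF-kB genes (-0.66) and growth factor receptors (-0.91). By the mean it gained androgen response (0.88), luminal markers (1.93) and neuroendocrine genes (-2.07).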

Other observations

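The groups described here were chosen after the data were seen, and their values are given without a test. Homeobox genes of the HOXA cluster summed to 6.5 normalised CPM in LNCAP, 131 CPM in PC3 and 86.2 CPM in DU145, with 2, 10 and 9 of 11 genes at 1 CPM or more. The HOXB cluster summed to 338, 479.9 and 126 CPM in the same order, and HOXB13 made up 329 CPM of it in LNCAP and 387 CPM in PC3, with no counts in DU145. The HOXC cluster summed to 70, 30 and 55.5 CPM, and the HOXD cluster to 0, 2.2 and 6.6 CPM.

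Of 1240 tested genes that the files assign to a transcription factor family, 166 were at least 4-fold higher and 171 lower in PC3 than in LNCAP, 177 and 159 in DU145, and 137 and 152 in PC3 against DU145. TFCP2 had no counts in LNCAP and stood at 70.3 CPM in PC3 and 56.0 CPM in DU145, and FOSL1 stood at 0.512, 527 and 124 CPM. GLI2, a Hedgehog pathway factor, and KLF12 also had no counts in LNCAP, with 23.6 and 55.9 CPM in PC3 and 34.3 and 20.9 CPM in DU145. In the other direction GRHL2 stood at 269, 0.523 and 0 CPM and ZBTB16 at 61.0, 0 and 0 CPM. Among non-coding genes, LINC00857 had no counts in LNCAP and 69.2 and 43.3 CPM in PC3 and DU145. MIR99AHG had 753 counts in LNCAP and none in the others. PCA3, a prostate cancer marker transcript, had 287 counts in LNCAP and none in the others, and COLCA1 stood at 353, 0 and 0.447 CPM; both are annotated as antisense, and their values are uncertain without strand information. Of 956 tested lincRNA genes 115 were higher and 156 lower in both lines, and of 1147 antisense genes, with the same uncertainty, 82 and 123.

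Protein-coding genes with 3 counts or fewer in 1 line and 5 CPM or more in both others were also counted for LNCAP and DU145. LNCAP had 170 such genes of 9912, with 10 neighbouring pairs where random placement gave a mean of 2.88 and 8 of 10000 placements gave as many. DU145 had 41 of 9552, with 3 neighbouring pairs, a number reached by 7 placements, and 1 pair without its longest run, reached by 1554. That run held PRAC1, PRAC2 and HOXB13 on chromosome 17 (48721719 to 48729178), with 0 counts in DU145 over its 6 annotated genes, 5490 in LNCAP and 6343 in PC3.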
